A study of Mus musculus with 8 samples.

How the data were processed

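Gene expression was measured in the cerebellum of mouse embryos at embryonic day 17.5 on Illumina BeadArrays, from total RNA amplified into biotin-labelled cRNA, per the labels' protocols. The groups were 4 wild-type (WT) animals, homozygous for the floxed Pals1 allele and without Cre, and 4 conditional knockout (CKO) animals with the same allele and hGFAP-Cre, a transgene that expresses Cre recombinase in most cerebellar neurons and glia, per the series design. Groups and replicate numbers were taken from the sample titles and genotypes. The animals are the replicates.

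The first deposited table holds a linear intensity per probe and array, exported from BeadStudio per the labels and the submitters' processing notes, with no version of the software and no scanner background handling given in the sources used here. Array medians of this intensity differed, so the table was taken as not normalized between arrays. It was read without detection p-values. The second deposited table holds log2 values of the same arrays, and per its values the authors quantile-normalized them: every array has a median of 6.98, and each value equals the log2 of the quantile-normalized intensity to within 0.005. The tool behind that step is not given in the sources used here. The tables list 25697 probes. A gene symbol came from the platform annotation for 23978 probes, 0 probes had several symbols, and 1719 probes have no gene name here. The named probes cover 16593 symbols. Symbols are those of the annotation, and no coordinates are given because the genome build behind the probes is not given in the sources used here.

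The intensities were analysed with limma 3.58.1 in R 4.3.3. Background was corrected by the normexp method with an offset of 50, arrays were quantile-normalized and values were taken to the log2 scale. The design written before the data were examined had named limma's neqc and a filter on detection p-values. It also named this offset and a brightness filter for a table without detection p-values, and that fallback was used. A gene is represented by its probe with the highest mean over the 8 arrays, a rule set after the probes of the targeted gene had been seen. Genes were tested where that mean exceeded the lower quartile over all probes, a log2 level of 6.26, which left 12912 genes. An offset of 50 pulls the changes of dim genes towards 0, and filtered genes are described as not tested. Linear models with genotype as the only term were fitted with lmFit and eBayes, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values of genes in the text come from this limma fit unless another setting is named. For the targeted gene an exact two-sided permutation test over all 70 assignments of the arrays was added.

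A total of 25 gene lists with 580 symbols, 504 of them on the array, were fixed before the data were examined, as were the tests, the first set of alternatives and the rule for naming genes. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, with camera at an estimated correlation and with fry beside it. Counts "adjusted over the list alone" use only the p-values of that list's members. The naming rule took the targeted gene, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and from each list up to 4 members past the threshold with the largest change, filled to 2 by smallest p where fewer passed. Sex-linked markers stayed out of the largest changes. This gave 99 genes. A further 31 genes were named after their values were seen, to complete small counts.

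Before use, the fit was tested on simulated data: among 12912 genes of the CKO against WT comparison with 200 changed, 82% of the 100 changes of 0.5 log2 and 100% of the 100 changes of 1 log2 were recovered. The simulation gave 4 false calls, 2.15% of all calls, found the shifted list and called 0 others. Its noise was drawn independently for each gene, so it does not show how often correlated genes give false list calls. In the data the estimated correlation was 0.47 for DNA replication and 0.64 for mitosis. The alternatives covered background correction, normalization, the authors' log2 values, filters, the probe rule, array weights, variance moderation, a replicate block, leaving out each array, and the Xist level as a covariate. The detection p-value filter and a chip block were not run, because the columns used here carry neither detection p-values nor chip names. For arrays, their number limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.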

Results

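The series asked what loss of Pals1 does to dividing progenitors of the embryonic cerebellum. Pals1, encoded by Mpp5, is a scaffold protein of the apical Crumbs polarity complex. Cerebella of 4 WT and 4 CKO animals were profiled at embryonic day 17.5, an array per animal. Median raw intensities were 131.9, 132.3, 124.1 and 125.3 on the WT arrays and 133.5, 118.7, 128.0 and 118.8 on the CKO arrays, in order of replicate number. Log2 levels correlated across genes between 0.991 and 0.997 within groups and between 0.983 and 0.990 across groups. The first principal component held 49.6% of the variance and separated the groups, and the second held 16.1% and set CKO.3 apart. Xist, the RNA of the inactive X chromosome, was bright in WT.1, WT.2 and WT.4 and dim in WT.3 and all 4 CKO arrays, and the Y-linked gene Eif2s3y had the opposite pattern, so these markers of sex were unevenly spread over the groups.

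Mpp5 was lower on every CKO array than on every WT array. Its brighter probe, ILMN_2594593, had raw intensities of 156.2, 152.7, 143.8 and 139.7 in WT and 92.8, 80.2, 87.0 and 77.5 in CKO. On the normalized log2 scale Mpp5 was 7.06 ± 0.035 (SD, n = 4) in WT and 6.20 ± 0.088 (SD, n = 4) in CKO. It fell by 0.87 on the log2 scale (SE 0.07, 95% interval -1.01 to -0.72, limma adjusted p = 8.43e-06), and an exact permutation test gave p = 0.0286, the smallest the 70 assignments allow. The probe lay at percentiles 54.2 to 55.7 of the WT arrays and 13.1 to 25.8 of the CKO arrays, so that the CKO level is close to background. With an offset of 16 the change was -1.34 (adjusted p = 3.27e-05, within a range of 5.49e-07 to 0.00334 over the alternatives). The other probe, ILMN_2590811, was below the filter on brightness in both groups. Where the probes lie relative to the deleted exons is not known here.

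Expression differed widely between the genotypes: genes of cell division and of granule cell progenitors were lower in CKO, and genes of the p53 response, Purkinje cells, synapses and microglia were higher. Of the lists behind this statement, only that of p53 kept its camera call when the correlation between genes was estimated (adjusted p = 0.0127). The other lists named had adjusted p of 0.106 to 0.140, at estimated correlations of 0.06 to 0.64. For p53 the estimate, 0.0015, was below the preset 0.01, yet its camera adjusted p rose from 2.71e-09. A higher correlation thus does not account for every rise in p. In the fry test, which asks for a shift within each list alone, all these lists were called (adjusted p = 1.14e-05 to 0.00304). Of 12912 genes tested, 1182 were higher and 1115 lower in CKO at the adjusted threshold, 17.8% in all, with a median absolute change of 0.36 on the log2 scale among them. Falls were the larger changes, with 57 genes lower and 9 higher by at least 2-fold. The groups did not overlap for 2732 genes, 21.2% against the 2.86% that chance gives, and 2014 of these were also past the threshold. With median scaling in place of quantile normalization, 792 genes were higher and 1337 lower. With the Xist level as a covariate 363 were higher and 430 lower, and 687 of the main calls were shared. Under that covariate 58 of 129 named genes lost their call. Without both WT.3 and CKO.3 the counts were 1147 and 1181, with 1914 calls shared. Standard errors of the 115 named genes past the threshold, sex markers left out, lay between 0.06 and 0.30 on the log2 scale, with 4 arrays per group.

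**Figure D1:**
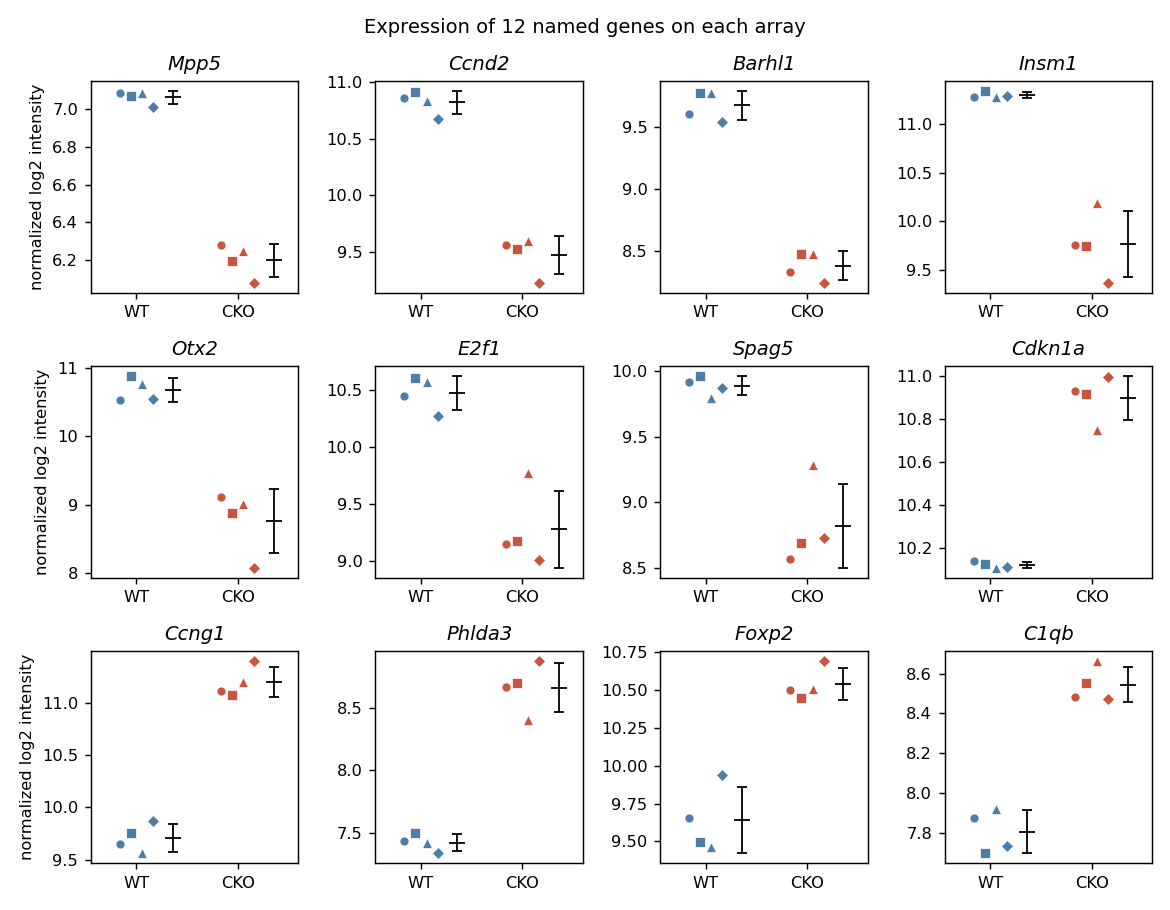
Normalized log2 levels of 12 genes on each of the 8 arrays (WT blue, CKO red, marker shapes for replicates 1 to 4, bars for mean ± SD). Mpp5, Ccnd2, Barhl1, Insm1, Otx2, E2f1 and Spag5 are lower in CKO, and Cdkn1a, Ccng1, Phlda3, Foxp2 and C1qb are higher.

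Genes of DNA replication fell almost as a whole. Of 31 tested members 26 fell and 0 rose, with a median change of -0.75 on the log2 scale (camera adjusted p = 9.79e-23; adjusted p = 0.12 with an estimated correlation, within a range of 8.89e-28 to 0.12 over the alternatives). Adjusted over the list alone, 27 fell. E2f1, the transcription factor that drives entry into S phase, fell by 1.20 (adjusted p = 1.63e-04). Cdt1, which loads the replicative helicase, fell by 1.05 (adjusted p = 2.57e-04), Uhrf1, which keeps DNA methylation through replication, by 1.03 (adjusted p = 4.18e-04) and Tk1, thymidine kinase, by 0.98 (adjusted p = 8.65e-04). The 5 members not past the threshold, named after their values were seen, were Mcm6 (-1.72, adjusted p = 0.139), Pcna (-0.14), Prim1 (-0.11), Ccne1 (0.08) and Dut (-0.01). The Prim1 probe was dim in both groups (log2 level 6.83 in WT, 6.72 in CKO), which left little room to see a fall. The chosen Mcm6 probe, for a subunit of the replicative helicase, read 5.98 in CKO.3 against 9.66 to 10.55 on the other CKO arrays. Without CKO.3 Mcm6 changed by -0.67 (adjusted p = 0.0504, within a range of 0.00253 to 0.380 over the alternatives). Its other 3 probes changed by -0.92, -0.84 and -0.39, each past the threshold over all probes. Pola1, Slbp and Orc1 were not tested.

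Genes of mitosis fell in the same way, with 22 of 25 tested members lower, 0 higher and a median change of -0.83 (camera adjusted p = 1.36e-18; adjusted p = 0.14 with an estimated correlation, within a range of 3.32e-26 to 0.14 over the alternatives). Adjusted over the list alone, 22 fell. Kif22, a chromosome-bound kinesin, fell by 1.19 (adjusted p = 2.56e-04), Cenpa, the centromeric histone, by 1.09 (adjusted p = 5.44e-04), Spag5, a spindle protein, by 1.06 (adjusted p = 1.75e-04) and the mitotic kinase Plk1 by 1.10 (adjusted p = 0.0210). Plk1 lost its call without WT.1, WT.2, CKO.1, CKO.2 or CKO.4 (adjusted p from 0.0548 to 0.0741, within a range of 1.85e-04 to 0.575 over the alternatives). With the mean of a gene's probes, Spag5 changed by -0.47 and Uhrf1, of the replication list, by -0.64. The 3 members not past the threshold, named after their values were seen, were Kif20a (0.14), Ttk (0.04) and Ube2c (-0.02). Ttk (log2 level 6.34 in WT, 6.38 in CKO) and Ube2c (6.71 and 6.69) lay below the median probe, 6.84. Their probes thus left little room to see a fall. CKO.3 differed from the other CKO arrays in these groups: the mean deviation of mitosis genes from the 8-array mean was 0.00026 in CKO.3 and -0.57 to -0.43 in the other CKO arrays, against 0.31 to 0.49 in WT. For DNA replication genes it was -0.19 in CKO.3 and -0.44 to -0.33 in the others.

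Markers of granule cell progenitors, the dividing cells of the external granular layer, were lower in CKO. Of 13 tested members 12 fell and 0 rose, with a median change of -0.61 (camera adjusted p = 2.03e-10; adjusted p = 0.106 with an estimated correlation, within a range of 2.10e-11 to 0.106 over the alternatives). Adjusted over the list alone, 12 fell and 1, Lhx9, rose. Mfap4, a microfibril protein listed for these cells, fell by 1.84 (adjusted p = 5.17e-04) and Insm1, a zinc-finger factor of neuronal progenitors, by 1.53 (adjusted p = 1.71e-05). Ccnd2, the D-type cyclin of these progenitors, fell by 1.34 (adjusted p = 2.80e-06) and the homeobox factor Barhl1 by 1.30 (adjusted p = 2.05e-06). Lhx9, named after its values were seen, was at 0.22 (adjusted p = 0.0796) and passed without WT.4 or CKO.3 (adjusted p from 0.0453 to 0.0484, within a range of 0.0366 to 0.221 over the alternatives). Atoh1, Pax6, Lhx2, Gli1 and Mycn were not tested. The mean deviation of this list was -0.16 in CKO.3 and -0.50 to -0.42 in the other CKO arrays, against 0.27 to 0.49 in WT.

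The list of the Sonic hedgehog (Shh) pathway, which drives division of granule cell progenitors, was lower by a smaller margin. Of 17 tested members 6 fell and 1 rose, with a median change of -0.12 (camera adjusted p = 0.0321; adjusted p = 0.131 with an estimated correlation, within a range of 8.82e-04 to 0.157 over the alternatives), and adjusted over the list alone 6 fell and 2 rose. The estimated correlation of this list, -0.02, was below the preset 0.01, so a higher correlation was not what cost the call there. The fry test kept the call (adjusted p = 8.82e-04). The camera call was also lost with the filter at the median probe (adjusted p = 0.111) and with the Xist covariate (adjusted p = 0.157). Of the 6 that fell, 3 (Ccnd2, Ccnd1 and Sfrp1) also stand in the list of granule cell progenitors, so the lists are not separate evidence. Outside these, Smo, the signal transducer, fell by 0.52 (adjusted p = 0.00777). Of the shared genes Sfrp1, a secreted Wnt modulator, fell by 0.64 (adjusted p = 0.0287) but lost its call without any single array other than WT.4 and CKO.3 (adjusted p from 0.0638 to 0.0919, within a range of 0.00207 to 0.124 over the alternatives). Nkx2-2, a homeobox factor, fell by 0.43 (adjusted p = 0.0317) and lost its call without WT.1, WT.2, WT.3, CKO.1 or CKO.2 (adjusted p from 0.0797 to 0.105, within a range of 0.00142 to 0.249 over the alternatives). Shh, the ligand itself and named after its values were seen, rose by 0.41 (adjusted p = 8.65e-04). The list level was 0.03 in CKO.3 and -0.13 to -0.12 in the other CKO arrays.

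Targets of p53 rose. Of 22 tested members of the p53 and apoptosis list 14 rose and 1 fell, with a median change of 0.38, and adjusted over the list alone 15 rose and 2 fell. Of the 11 lists called it was the only one whose call held with an estimated correlation (camera adjusted p = 2.71e-09; adjusted p = 0.0127 with an estimated correlation, within a range of 1.08e-10 to 0.0127 over the alternatives). Ccng1, an atypical cyclin induced by p53, rose by 1.49 (SE 0.09, adjusted p = 2.05e-06), Ddit4l, an inhibitor of mTOR signalling, by 1.47 (SE 0.10, adjusted p = 3.42e-06), and Phlda3, a p53-induced inhibitor of Akt, by 1.24 (SE 0.09, adjusted p = 5.07e-06). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 0.78 (SE 0.07, adjusted p = 2.18e-05). Sesn1, a stress-induced sestrin named after its values were seen, fell by 0.41 (adjusted p = 0.0106), or -0.24 as the mean of its probes. The list's mean deviation was 0.18 to 0.26 in CKO, CKO.3 included, against -0.23 to -0.17 in WT.

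Regulators of cell cycle exit were not past the camera test as a list (16 tested members, median change -0.0037, camera adjusted p = 0.383). Of its members 2 rose and 4 fell, or 3 and 6 adjusted over the list alone. Beside Cdkn1a, the factor Klf4, named after its values were seen, rose by 0.21 (adjusted p = 0.0390). The stress protein Gadd45g fell by 0.75 (adjusted p = 4.26e-04), the kinase inhibitors Cdkn2c and Cdkn1b fell by 0.57 (adjusted p = 8.94e-04) and 0.51 (adjusted p = 0.00720), and Rbl1, the pocket protein p107 named after its values were seen, fell by 0.48 (adjusted p = 0.0139). As the mean of their probes Cdkn2c changed by -0.34, Cdkn1b by -0.32 and Klf4 by 0.11, the last no longer past the threshold. Klf4 also lost its call without any single array other than WT.3 (adjusted p from 0.0532 to 0.0986, within a range of 0.0211 to 0.481 over the alternatives).

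Purkinje cell genes were mostly higher in CKO, with 9 of 17 tested members higher, 2 lower and a median change of 0.38 (camera adjusted p = 8.18e-05; adjusted p = 0.115 with an estimated correlation, within a range of 2.90e-05 to 0.115 over the alternatives). Adjusted over the list alone, 10 rose and 2 fell. Foxp2, a forkhead factor of these neurons, rose by 0.90 (adjusted p = 1.27e-04), Ebf2 by 0.86 (adjusted p = 4.16e-05) and the nuclear receptor Rora by 0.68 (adjusted p = 5.83e-05). The calcium buffer Pvalb fell by 1.30 (adjusted p = 5.37e-04). The patterning gene En1, named after its values were seen, fell by 0.27 (adjusted p = 0.0190) and lost its call without CKO.4 (adjusted p = 0.0622, within a range of 0.0133 to 0.166 over the alternatives).

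Genes of synapses and neuronal maturation rose by smaller amounts. Of 25 tested members 13 rose and 0 fell, with a median change of 0.31 (camera adjusted p = 3.07e-08; adjusted p = 0.12 with an estimated correlation, within a range of 5.86e-09 to 0.12 over the alternatives), and adjusted over the list alone 19 rose. The secretory granule protein Chgb rose by 0.45 (adjusted p = 0.00417), the neurofilament Nefm by 0.44 (adjusted p = 0.00231), the synaptic vesicle protein Syn1 by 0.41 (adjusted p = 0.00359) and the kinase subunit Camk2b by 0.39 (adjusted p = 0.00114). Genes of postmitotic granule neurons went the other way: 7 of 17 tested members fell and 1 rose, with a median change of -0.15 (camera adjusted p = 4.61e-04; adjusted p = 0.14 with an estimated correlation, within a range of 1.08e-04 to 0.14 over the alternatives), or 8 and 1 adjusted over the list alone. This call was also lost with the Xist covariate (adjusted p = 0.0910). The nuclear factors Nfix and Nfib fell by 1.24 (adjusted p = 2.80e-06) and 0.82 (adjusted p = 4.61e-05), the secreted guidance protein Reln by 0.53 (adjusted p = 6.29e-04) and the neurogenic factor Neurod2 by 0.52 (adjusted p = 0.00240). With the mean of a gene's probes Nfix changed by -0.74. Dcx, a microtubule protein of migrating neurons named after its values were seen, rose by 0.35 (adjusted p = 0.00865).

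Markers of microglia and macrophages were higher in CKO, with 12 of 23 tested members higher, 0 lower and a median change of 0.32 (camera adjusted p = 3.90e-08; adjusted p = 0.106 with an estimated correlation, within a range of 1.14e-09 to 0.106 over the alternatives). Adjusted over the list alone, 14 rose. Lyz1, a lysozyme of phagocytes, rose by 1.05 (adjusted p = 1.84e-05), the complement subunit C1qb by 0.74 (adjusted p = 7.08e-05), the immunoglobulin receptor Fcgr3 by 0.73 (adjusted p = 0.0210) and Aif1, the microglial marker Iba1, by 0.63 (adjusted p = 2.08e-04). Fcgr3 lost its call without WT.2, WT.4 or CKO.4 (adjusted p from 0.0563 to 0.0734, within a range of 0.00499 to 0.489 over the alternatives). With the mean of a gene's probes Aif1 changed by 0.41. Its second probe, ILMN_2804487, nearly as bright, was at 0.19 and did not pass (limma adjusted p = 0.268 over all probes). The list's mean deviation was 0.12 to 0.29 in CKO, with CKO.3 the highest, against -0.23 to -0.11 in WT.

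**Figure D2:**
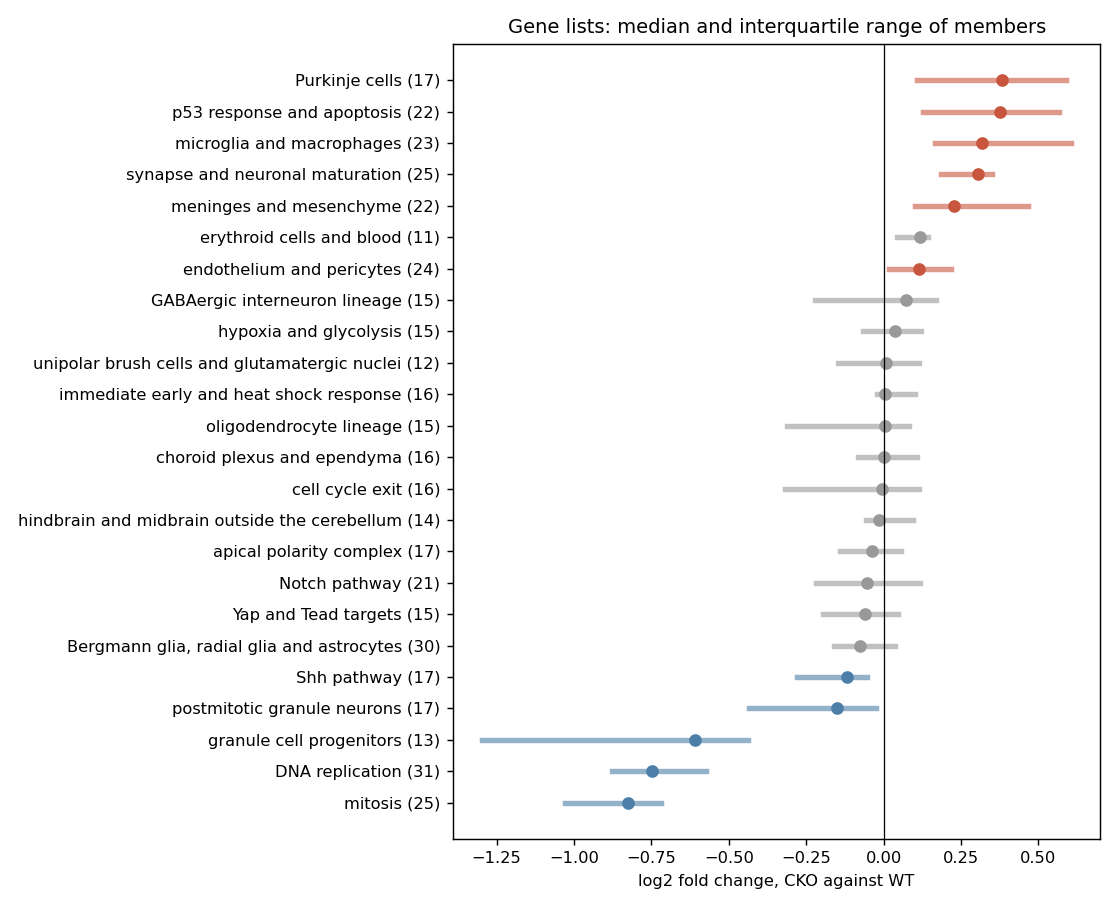
Log2 change of the tested members of 24 gene lists in CKO against WT, as the median (point) and interquartile range (line), with member counts in parentheses. Lists whose camera test was past the threshold are red where higher and blue where lower, others are grey, and the lowest medians are those of mitosis (-0.83) and DNA replication (-0.75).

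The lists of vascular and meningeal markers passed the camera test with few changed members, and both calls were lost under several alternatives. For endothelium and pericytes 4 of 24 tested members rose, 0 fell and the median change was 0.11 (camera adjusted p = 0.0240; adjusted p = 0.383 with an estimated correlation, within a range of 0.00583 to 0.383 over the alternatives), or 5 and 0 adjusted over the list alone. The call was lost without WT.3 (adjusted p = 0.0782) or CKO.3 (adjusted p = 0.161), with array weights (adjusted p = 0.0702) and in the fry test (adjusted p = 0.0935). Vtn, the adhesion protein vitronectin, rose by 0.52 (adjusted p = 0.0143), the sialomucin Emcn by 0.35 (adjusted p = 0.0249), the pericyte potassium channel Kcnj8 by 0.25 (adjusted p = 0.0225) and Pecam1, an endothelial adhesion molecule, by 0.20 (adjusted p = 0.0489). Emcn lost its call without WT.1, WT.2 or CKO.1 (adjusted p from 0.0596 to 0.0850), Kcnj8 without WT.3, CKO.2 or CKO.4 (adjusted p from 0.0549 to 0.0663) and Pecam1 without any single array (adjusted p from 0.0612 to 0.125). Over all alternatives the adjusted p of these 3 genes lay between 0.0135 and 0.316.

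For meninges and mesenchyme 1 of 22 tested members rose and 2 fell, also adjusted over the list alone, while the median change was 0.23 (camera adjusted p = 0.0476; adjusted p = 0.640 with an estimated correlation, within a range of 0.00661 to 0.640 over the alternatives). The list's mean deviation was 0.82 in CKO.3 and -0.14 to -0.04 in the other CKO arrays. Without CKO.3 its median change was 0.08 (adjusted p = 0.386), and the call was also lost without WT.1 (adjusted p = 0.131) or WT.3 (adjusted p = 0.0623). It was lost as well with no background correction (adjusted p = 0.0553), the authors' values (adjusted p = 0.0560), the filter at the median probe (adjusted p = 0.411), array weights (adjusted p = 0.156), the Xist covariate (adjusted p = 0.301) and fry (adjusted p = 0.388). Mfap2, a microfibril protein, fell by 0.50 (adjusted p = 0.00128). Igfbp2, which binds insulin-like growth factors, fell by 0.33 (adjusted p = 0.0310) and the retinoic acid carrier Crabp2 rose by 0.24 (adjusted p = 0.0357). Igfbp2 lost its call without any single array other than WT.1, CKO.2 and CKO.3 (adjusted p from 0.0576 to 0.0966), and Crabp2 without any other than WT.3 and CKO.2 (adjusted p from 0.0711 to 0.103). Over all alternatives the adjusted p of these 2 genes lay between 0.00633 and 0.675.

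Erythroid genes were not past the camera test as a list (11 tested, median change 0.12, or 0.02 without WT.2 and 0.06 without CKO.3, camera adjusted p = 0.276): Mkrn1, a ubiquitin ligase, rose by 0.34 (adjusted p = 0.00498), also when adjusted over the list alone, and the carbonic anhydrase Car2 was at 0.15 (adjusted p = 0.241). Genes of choroid plexus and ependyma were not either (16 tested, camera adjusted p = 0.673), with a median change of 0.00028 where the mean, -0.16, and the test pointed down. Otx2, a homeobox factor, fell by 1.91 (SE 0.18, adjusted p = 4.16e-05) and Ttr, transthyretin, by 1.09 (adjusted p = 0.0168), the same count adjusted over the list alone. Ttr lost its call without WT.4 (adjusted p = 0.0513) or CKO.4 (adjusted p = 0.0557), within a range of 1.89e-05 to 0.317 over the alternatives. Otx2 was also the 1 of 14 tested hindbrain and midbrain genes that changed (camera adjusted p = 0.941; the same adjusted over the list alone). Hoxa4, a hindbrain gene, was at 0.23 (adjusted p = 0.0977) and passed without CKO.3 (adjusted p = 0.0357, within a range of 0.0357 to 0.260 over the alternatives). Medians of other lists not past the camera test also moved when single arrays were left out: between -0.02 and 0.04 for choroid plexus, -0.04 and 0.03 for cell cycle exit, -0.08 and -0.04 for Bergmann glia, -0.05 and 0.04 for oligodendrocytes, 0.03 and 0.11 for the GABAergic lineage and -0.07 and 0.06 for unipolar brush cells.

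**Figure D3:**
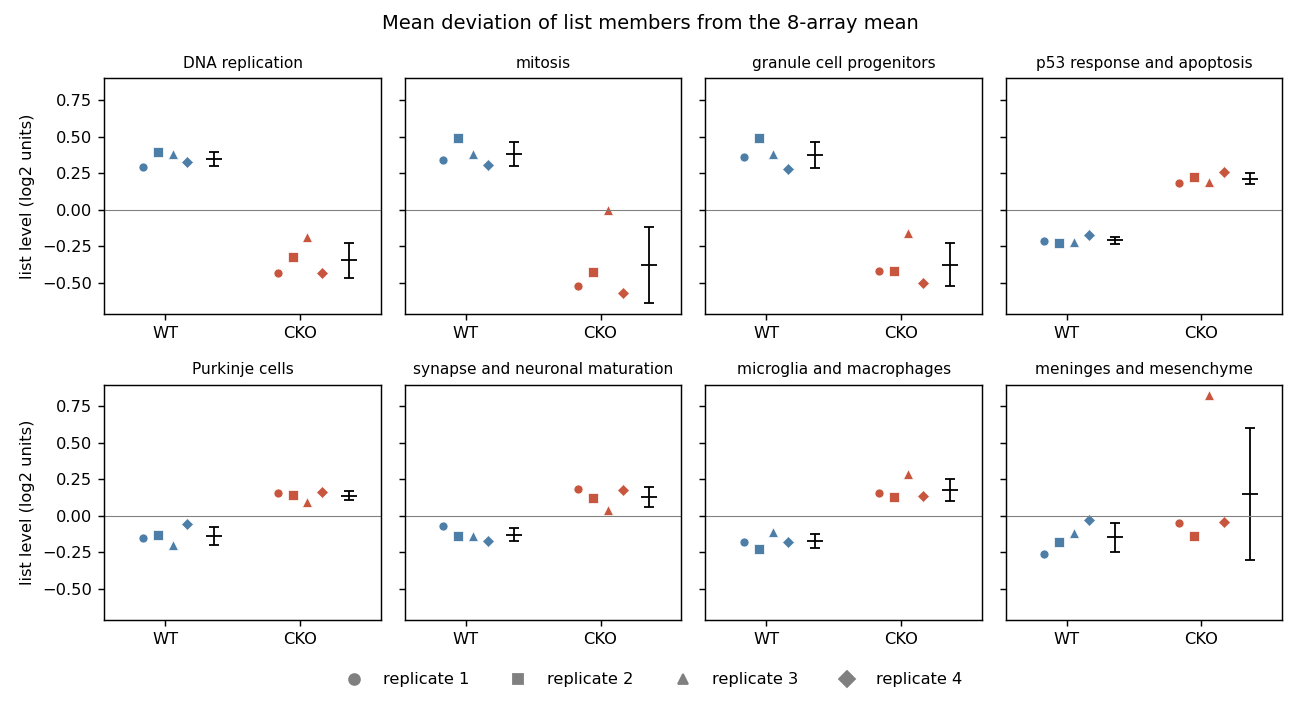
Mean deviation of the members of 8 gene lists from the 8-array mean, in log2 units, on each array (WT blue, CKO red, marker shapes for replicates 1 to 4, bars for mean ± SD). CKO.3 is at 0.00026 for mitosis and 0.82 for meninges and mesenchyme, apart from the other CKO arrays, and at 0.19 for p53 response and apoptosis, among them.

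The apical polarity complex, to which Pals1 belongs, was not past the camera test against other genes (17 tested, 2 higher and 3 lower, the same adjusted over the list alone, camera adjusted p = 0.276). The fry test, which asks for a shift within the list alone and here includes Mpp5, pointed down (adjusted p = 5.78e-04, within a range of 5.78e-04 to 0.730 over the alternatives). Besides Mpp5, Llgl1, a basolateral polarity protein, fell by 0.49 (adjusted p = 0.00125), and Patj, a direct partner of Pals1, fell by 0.31 (adjusted p = 0.0192). The atypical kinase C gene Prkcz rose by 0.41 (adjusted p = 0.00373), as did Lin7b, a partner of Pals1 named after its values were seen, by 0.28 (adjusted p = 0.0438). Patj lost its call without WT.1, WT.3 or CKO.4 (adjusted p from 0.0560 to 0.0577, within a range of 0.00797 to 0.130 over the alternatives), and Lin7b without any single array other than WT.3 (adjusted p from 0.0704 to 0.138, within a range of 0.00805 to 0.908). As the mean of their probes Patj changed by -0.20 and Lin7b by 0.17, both no longer past the threshold.

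Notch pathway genes split (21 tested, 3 higher and 4 lower, camera adjusted p = 0.207; 3 and 5 adjusted over the list alone), while fry pointed down (adjusted p = 0.00644, within a range of 0.00644 to 0.283 over the alternatives). The fringe enzyme Mfng fell by 1.16 (adjusted p = 8.13e-04), or -0.71 as the mean of its probes. The transcriptional repressors Hey1 and Hes6 fell by 0.96 (adjusted p = 8.02e-05) and 0.77 (adjusted p = 3.08e-04), and the receptor Notch1 by 0.35 (adjusted p = 0.0150). The 3 that rose, named after their values were seen, were the ligand Jag2 (0.23), Dtx1 (0.31) and the fringe enzyme Rfng (0.28). Notch1 lost its call without WT.2 (adjusted p = 0.0519) or CKO.4 (adjusted p = 0.0503), Jag2 without any single array other than WT.3 and CKO.3 (adjusted p from 0.0608 to 0.117), and Dtx1 and Rfng without any other than CKO.3 (adjusted p from 0.0502 to 0.137). Over all alternatives the adjusted p of these 4 genes lay between 0.00311 and 0.450. Among Yap and Tead targets 3 of 15 tested fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0997; past the threshold without CKO.1, adjusted p = 0.0310, and in the fry test, adjusted p = 0.00644, within a range of 0.00644 to 0.255 over the alternatives). These were the transcription factor Tead2 (-1.07, adjusted p = 1.16e-04), the Hippo scaffold Wwc1 (-0.50, adjusted p = 0.00135) and the kinase Nuak2 (-0.41, adjusted p = 7.87e-04).

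Genes of Bergmann glia, radial glia and astrocytes were not past the camera test as a list (30 tested, 2 higher and 5 lower, 2 and 7 adjusted over the list alone, median change -0.07, camera adjusted p = 0.160), while fry pointed down (adjusted p = 0.0277, within a range of 0.0277 to 0.511 over the alternatives). Etv5, an effector of growth factor signalling, fell by 0.58 (adjusted p = 0.00307), the water channel Aqp4 by 0.47 (adjusted p = 0.00947) and the intermediate filament Vim by 0.37 (adjusted p = 0.0134), and Id4 rose by 0.41 (adjusted p = 0.00141). Named after their values were seen, Pla2g7 (-0.35) and Etv4 (-0.25) fell and Tnc (0.32), an extracellular matrix protein, rose. Pla2g7 lost its call without WT.2, WT.4, CKO.1, CKO.2 or CKO.4 (adjusted p from 0.0564 to 0.0931), Etv4 without any single array other than CKO.3 (adjusted p from 0.0575 to 0.0908) and Tnc without CKO.1 (adjusted p = 0.0611) or CKO.2 (adjusted p = 0.0566). Over all alternatives the adjusted p of these 3 genes lay between 0.00398 and 0.397. The oligodendrocyte list (15 tested, 1 higher and 3 lower, 1 and 5 adjusted over the list alone, camera adjusted p = 0.291) had a median change of 0.0045 where the mean, -0.08, and the test pointed down. Pdgfra, the receptor of oligodendrocyte precursors, fell by 0.98 (adjusted p = 0.00206) and Gpr17 by 0.67 (adjusted p = 8.08e-04), with Nkx2-2 the other that fell. Bmp4, a growth factor, rose by 0.30 (adjusted p = 0.0147) and lost its call without CKO.4 (adjusted p = 0.05004, within a range of 0.00886 to 0.231 over the alternatives).

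In the GABAergic lineage 3 of 15 tested members rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.941), with a median change of 0.07 where the mean, -0.05, and the test pointed down. The progenitor factors Ptf1a, Neurog2 and Gsx1 fell by 0.96 (adjusted p = 1.68e-04), 0.68 (adjusted p = 0.00331) and 0.44 (adjusted p = 0.00355). The neuropeptide Cck rose by 0.47 (adjusted p = 0.00191), and so did, named after their values were seen, the vesicular GABA transporter Slc32a1 (0.36, adjusted p = 0.00663) and the neuropeptide Sst (0.34, adjusted p = 0.0117). Among unipolar brush cell and glutamatergic nuclei genes 2 of 12 tested rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.941), with a median change of 0.0066 where the mean, -0.06, and the test pointed down. Eomes, a marker of unipolar brush cells, fell by 1.26 (adjusted p = 7.66e-05) and Pou4f1 by 0.35 (adjusted p = 0.0292), while Tbr1, a marker of glutamatergic nuclei, rose by 0.49 (adjusted p = 0.00152) and Meis2 by 0.45 (adjusted p = 0.00614). Pou4f1 lost its call without WT.1, WT.4, CKO.3 or CKO.4 (adjusted p from 0.0503 to 0.0894, within a range of 0.0130 to 0.313 over the alternatives).

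Lists of acute stress and of hypoxia showed single changes. Of 16 tested immediate early and heat shock genes Egr1 rose by 0.69 (adjusted p = 0.00471) and 0 fell, also adjusted over the list alone (camera adjusted p = 0.489), and Arc was at 0.22 (adjusted p = 0.102), passing without CKO.3 (adjusted p = 0.0326, within a range of 0.0326 to 0.492 over the alternatives). Of 15 tested hypoxia and glycolysis genes the lactate dehydrogenase gene Ldha fell by 0.42 (adjusted p = 0.00778) and the glycolytic regulator Pfkfb3 rose by 0.24 (adjusted p = 0.0270), the same adjusted over the list alone (camera adjusted p = 0.856). Pfkfb3 lost its call without WT.1, WT.4, CKO.1 or CKO.2 (adjusted p from 0.0672 to 0.0749, within a range of 0.0188 to 0.296 over the alternatives). Of the 4 tested sex markers Eif2s3y (2.71, adjusted p = 0.00299) and Kdm5d (0.89, adjusted p = 0.0173) were higher and Xist (-2.45, adjusted p = 0.00699) lower, the same adjusted over the list alone (camera adjusted p = 0.276). On WT.1, WT.2 and WT.4 Eif2s3y read 5.94 to 6.05 and Kdm5d 6.19 to 6.37, near background. The size of both rises thus depends on the treatment of background. Kdm5d lost its call without WT.1, WT.2, WT.4 or CKO.4 (adjusted p from 0.0527 to 0.0576, within a range of 1.70e-04 to 0.951 over the alternatives).

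The largest single change was that of Prm1, the protamine of spermatids, which rose by 7.20 on the log2 scale (SE 0.10, adjusted p = 5.44e-14). Its raw intensity was 82.9 to 95.5 on the WT arrays and 8907.6 to 12266.8 on the CKO arrays. Its WT mean of 6.25 on the log2 scale lay under the filter level of 6.26, near background, so the size of the rise is set by the treatment of background (8.05 with an offset of 16, 6.99 with no background correction). Of the 12 largest rises, those outside the lists above were Prm1, the epoxide hydrolase Ephx1 (1.35, adjusted p = 2.05e-06), Pqlc3 (1.32, adjusted p = 7.13e-06), Cox6b2 (1.14, adjusted p = 3.36e-06), the matrix metalloproteinase Mmp2 (0.95, adjusted p = 2.56e-04), the interferon-induced membrane protein Ifitm3 (0.92, adjusted p = 0.00131) and the adaptor Sla (0.87, adjusted p = 5.92e-05). The WT mean of Pqlc3, 6.16, was also near background, so that its size and place among the rises depend on the treatment of background (1.96 with an offset of 16, 1.19 with no background correction). With the mean of a gene's probes Pqlc3 changed by 0.73, Cox6b2 by 0.53 and Sla by 0.41. The dimmer Cox6b2 probe, ILMN_1229627, was at -0.08 (limma adjusted p = 0.768 over all probes), so the rise of Cox6b2 rests on its brighter probe. Of the 12 largest falls, those outside the lists were the mitochondrial protein Mgarp (-1.97, adjusted p = 1.16e-04), the elastin crosslinking enzyme Loxl1 (-1.91, adjusted p = 1.75e-04), Hsd11b2, which inactivates glucocorticoids (-1.72, adjusted p = 2.05e-06), the proneural factor Neurod4 (-1.44, adjusted p = 3.36e-06) and the Myc target Cdca7 (-1.39, adjusted p = 8.48e-05). The histone genes H2ac11 (-1.53, adjusted p = 1.91e-05), H2ac21 (-1.43, adjusted p = 3.93e-04), H2ac15 (-1.39, adjusted p = 2.93e-04) and H2ac12 (-1.39, adjusted p = 3.38e-04) completed them, and their near-identical sequences leave open which copy each probe measured.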

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

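The fit with the Xist level as a covariate was chosen after the data were seen. Single arrays were compared with the others of their group for each named gene and each list level, 310 groups in all, and an array far from the other 3 was found in 22 of them, where chance gives about 1 in 20, or 15.5. CKO.3 was the far array in 8 of these. It was higher than the other CKO arrays for Loxl1 (8.74 against 7.47 to 7.53), Tk1 (8.59 against 7.77 to 7.85), Plk1 (10.01 against 8.59 to 8.81), Sfrp1 (8.58 against 7.83 to 7.92) and Pdgfra (9.30 against 8.34 to 8.40). It was also higher for the levels of the Shh list (0.029 against -0.13 to -0.12), the Bergmann glia list (-0.0039 against -0.051 to -0.044) and the meninges list (0.82 against -0.14 to -0.04). Without WT.3 and CKO.3, 2328 genes were past the threshold.

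Other far arrays were spread over genes. In WT, WT.1 was low for Kif22 (10.87) and Bmp4 (6.47) and high for Usp18 (6.40), WT.2 was high for Ltbp3 (9.17), WT.3 was high for Ccne1 (8.10), and WT.4 was high for Egr1 (8.80) and Sesn1 (10.33). In CKO, CKO.1 was high for Sst (12.33), and CKO.4 was low for Nfix (9.25) and high for Id4 (10.50) and Shh (8.11). Of the probes without a gene name, which the report does not use, 159 were past the threshold when each probe was tested alone, 77 higher and 82 lower in CKO.

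WT.3 stood apart from the other WT arrays in the sex markers Xist (6.83 against 9.71 to 10.10), Eif2s3y (8.98 against 5.94 to 6.05) and Kdm5d (7.44 against 6.19 to 6.37), at the levels of the 4 CKO arrays, so an unequal sex of the embryos could account for part of the genotype differences. As the whole cause it is argued against: over 1828 genes called without WT.3, with the mean of the other WT arrays at 0 and the CKO mean at 1, WT.3 had a median position of 0.025 (quartiles -0.24 and 0.28), while single other WT arrays had medians of -0.04 to 0.17. With the Xist covariate the calls fell to 793, while the median absolute change of the called genes went from 0.358 to 0.396 and their median SE from 0.080 to 0.126. The fewer calls then go with larger errors, since the Xist level largely follows genotype. A share of sex in single genes stays open, and genotype remains the biological explanation that the design names. Genotype here joins loss of Pals1 with the Cre transgene, which only CKO animals carry, and the design cannot tell their effects apart.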

How the results depend on the processing

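An offset of 16, a filter at the median probe, the mean of a gene's probes, every probe alone, the Xist covariate and leaving out WT.3 with CKO.3 were chosen after the data were seen. The detection p-value filter and the chip block were not run, and with the filter at the median probe Mpp5 gave no value. Against 2297 genes past the threshold, 344 (90 higher, 254 lower) changed by at least 1.5-fold and 793 were past it with the Xist covariate, where errors grew; median scaling gave 2129 with 37.2% higher against 51.5%, and single arrays left out gave 1583 to 2564. The replicate numbers did not pair the arrays (correlations of same-numbered deviations -0.05 to 0.15), and a replicate block gave 2147 genes, 2019 of them shared. Mpp5 kept its direction and call in all 19 alternatives that gave a value, from -1.34 to -0.77, and from -0.89 to -0.83 with single arrays left out. With an estimated correlation the adjusted p was 0.120 for DNA replication, 0.140 for mitosis, 0.106 for granule cell progenitors and 0.131 for the Shh pathway. In the fry test these lists kept their calls (adjusted p = 8.82e-04, 0.00304, 5.77e-04 and 8.82e-04). The Shh median was -0.108 with the filter at the median probe and -0.100 with the Xist covariate, both without a call. The direction of the set test turned for 4 lists without a call. The median of a list can differ in sign from its test, so the medians below do not give the direction of the test. For the GABAergic list the median was then 0.0940 with the median-probe filter, 0.0731 with the mean of probes, 0.0968 with array weights, -0.0195 with the Xist covariate, 0.0563 without both arrays and 0.0317 to 0.112 with single arrays left out. For the hindbrain list it was -0.0257 with offset 16, -0.000915 with median scaling, 0.0108 with array weights and 0.107 with the Xist covariate. It was 0.00667 to 0.0193 without WT.1, WT.4, CKO.2 or CKO.3, each of which turned the test. For hypoxia it was 0.000477 with median scaling, 0.0301 without both arrays and 0.0140 to 0.0283 without WT.3 or CKO.4. For unipolar brush cells it was -0.0347 with median scaling, 0.0338 without a filter and with the median-probe filter, and 0.0416 with array weights. It was 0.0648 with the Xist covariate, 0.0279 without both arrays and 0.0140 to 0.0630 without WT.1, WT.4 or CKO.3. Over every single array left out, turned or not, the medians were -0.0363 to 0.0285 for hindbrain, 0.0140 to 0.0783 for hypoxia and -0.0748 to 0.0630 for unipolar brush cells. Among named genes the sign turned with the Xist covariate for Kdm5d (-0.0278), Ccne1 (-0.160), Kif20a (-0.0102), Pcna (0.199) and Ttk (-0.121), and for Dut with array weights (0.00671) and without both arrays (0.0346). With single arrays left out the values were -0.0365 to 0.0264 for Dut, -0.0777 to 0.0981 for Ttk and -0.142 to 0.0428 for Ube2c. Without a turn of sign, they were -0.244 to -0.0722 for Pcna, -0.157 to -0.0467 for Prim1 and 0.00567 to 0.157 for Ccne1. They were 0.0493 to 0.235 for Kif20a, 0.0959 to 0.197 for Car2 and 0.143 to 0.285 for Arc. Of the 99 genes named by rule 54 kept their call in every alternative that gave a value, and of the 31 others 6 did. The named genes past the threshold had 56 other probes above the filter. Of these probes 52 went in the same direction, 33 of them past the threshold over all probes, and 4 went the opposite way. With the Xist covariate, where errors grew, 58 of 129 named genes lost their call and 5 changed sign. With single arrays left out 134 of 1040 values lost the call. Median scaling, the next setting on all arrays, cost 13 calls. Why single genes lost their call was not tested. Mpp5, close to background in CKO, moved most with the offset, from -0.87 to -1.34.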

Other observations

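The gene groups in this part and the comparisons of microglia and Purkinje lists with other cell types were chosen after the results were seen. Of 58 tested histone genes of all types 26 fell and 2 rose, with a median change of -0.24 on the log2 scale. Of the linker histones only H1f10 fell (-0.49), and of the replacement variants H2az1 (-0.54) and H2ax (-0.50) fell while H3f3a (-0.04) and H3f3b (0.23) did not pass. Without the 4 genes among the largest falls that prompted the group, 22 of 54 fell (two-sided Fisher's exact test for falls, p = 1.61e-10, adjusted over the 6 tests of 3 such groups 9.66e-10). The genes that rose were H2aj (0.40) and H2bu2 (0.25), and H2bu2 lost its call without any single array other than WT.4 and CKO.2 (adjusted p from 0.0659 to 0.0985, within a range of 0.0245 to 0.155 over the alternatives). Histone copies are near identical and probes may share signal between them, which was not tested, so the genes are not independent.

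Of 17 tested genes of elastic fibres 5 fell and 1 rose. Without Loxl1 and Mfap4 3 of 15 fell, not past the threshold (two-sided Fisher's exact p = 0.134 for falls, adjusted 0.401). Loxl1 (-1.91) and Mfap4 (-1.84), which prompted the choice of the group, fell with the elastin gene Eln (-1.32), Ltbp3 (-1.0) and Mfap2 (-0.50). Emilin2 rose by 0.24 and lost its call without any single array other than WT.3 and CKO.4 (adjusted p from 0.0640 to 0.136, within a range of 0.0202 to 0.554 over the alternatives). Of 18 interferon and antigen presentation genes 3 rose, Ifitm3 (0.92), Bst2 (0.47) and Usp18 (0.39, or 0.64 with an offset of 16, its WT mean of 6.23 being near background), and 0 fell. Without Ifitm3, which prompted the group, 2 of 17 rose (two-sided Fisher's exact p = 0.665 for rises, adjusted 0.798). Bst2 lost its call without WT.2, WT.3, CKO.1 or CKO.2 (adjusted p from 0.0605 to 0.0728) and Usp18 without any single array other than WT.1, CKO.3 and CKO.4 (adjusted p from 0.0536 to 0.0619), and over all alternatives their adjusted p lay between 8.55e-04 and 0.185.

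Other splits of the 8 arrays into 4 and 4 were compared with the real one. For genes past the threshold, the DNA replication, mitosis, granule cell progenitor and Shh lists, 1 of the 35 splits, the real one, gave a result as large, the smallest share this design allows. This argues against chance, but the list p-values use the preset correlation, and with an estimated one the 4 list calls were lost (adjusted p = 0.120, 0.140, 0.106 and 0.131). In the fry test, which asks for a shift within each list alone, the 4 calls held (adjusted p = 8.82e-04, 0.00304, 5.77e-04 and 8.82e-04). The real split gave 2297 genes and the highest other 7. Every other split puts both genotypes in each group, which adds the genotype difference to the error. The gap between these counts thus does not measure chance. The camera p was 3.92e-24 against 1.70e-16 for DNA replication, 1.09e-19 against 1.31e-16 for mitosis, 2.44e-11 against 3.64e-07 for granule cell progenitors and 0.01285 against 0.01294 for Shh, a margin too narrow to carry weight for a call also lost with the median-probe filter and the Xist covariate. These smallest other p came from splits that exchanged a single array of each genotype. With both genotypes in equal number in each group, the smallest camera p were 4.43e-04, 4.20e-05, 0.0437 and 0.182 in the same order. For cell cycle exit 7 of 35 splits gave as small a p (0.291, against 0.165 for the smallest other), and chance cannot be excluded.

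Prm1 was bright on every CKO array and dim on every WT array, and a candidate explanation is that the Cre transgene, which only CKO animals carry, contains Prm1 sequence, as some transgene cassettes do for their polyadenylation signal. The lowest percentile of Prm1 on a CKO array was 99.3, against 15.9 to 32.4 on the WT arrays. A switched-on spermatid program is argued against, since 20 other spermatid genes had a median change of 0.017 (quartiles -0.030 and 0.10) and 0 of them passed the threshold. The transgene sequence itself was not examined here, and the hypothesis rests on the same arrays that raised it.

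A lower share of progenitors could raise the markers of every other cell type alike. Among members above the median probe, the microglia list's median change exceeded that of the endothelium, meninges and erythroid lists by 0.151 (95% bootstrap interval 0.058 to 0.437, 16 against 39 members), and by 0.211 without CKO.3. With the interval widened for the 7 references compared it was -0.010 to 0.504 and includes 0, and against meninges alone it was -0.260 to 0.443 before widening, with 6 of the 7 intervals above 0 before widening and 3 after. Without CKO.3 the widened interval against the same 3 lists was 0.042 to 0.521, and 4 of the 7 widened intervals lay above 0. Against glia the difference was 0.407 (widened interval 0.225 to 0.776). The intervals resample the genes of the lists with the arrays held fixed, so they measure spread between genes and not between animals. For these genes on these arrays the difference argues against an equal rise of every other cell type as the whole cause. A loss of both progenitors and glia stays open. More microglia and more activity per microglial cell were not separated by any test here.

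For the Purkinje list the difference from the same 3 lists was 0.292 (interval -0.059 to 0.510, 14 against 17 members with a log2 level above 8) and 0.502 without CKO.3 (interval 0.112 to 0.623), which leaves a lower share of progenitors undecided on all 8 arrays. Glia were then taken as a further reference, after that result: of 6 references compared, the interval lay above 0 for 1 on all 8 arrays, the glia list, and for 5 without CKO.3, or 1 in both cases after widening. Against glia the difference was 0.537, with an interval widened for the 6 comparisons of 0.076 to 0.806. This interval too measures spread between genes and not between animals. For these genes on these arrays the Purkinje list did not rise alike with the glia list. The glia list, whose median change was negative (-0.07), was taken after the results were seen. This comparison thus does not decide whether the other cell types rose alike. The glia list shares genes with progenitors, so a loss of both that raises the remaining types could still account for the difference from glia. More Purkinje cells and a change within them were not separated either.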
